A study of Mus musculus with 6 samples.

How the data were processed

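Gene expression was measured in lens ectoderm of mouse embryos at embryonic day 9.5, in 3 wild-type (WT) and 3 knockout (KO) samples. In the knockout, type I receptors for bone morphogenetic proteins (BMPs) had been deleted in the lens placode. The sample titles call the line ALK23, and ALK2 and ALK3 are the protein names of Acvr1 and Bmpr1a. Per the labels' protocols, embryos were frozen and cut into sections of 10 microns, and the lens ectoderm was isolated by laser microdissection after eosin staining. The tissue label of every sample reads more broadly, naming future lens or retina. An input of 15 ng went into a whole-transcriptome cDNA amplification, per the labels' protocols, and the cDNA was labelled with biotin for an Illumina BeadChip. The series text states that RNA was pooled and that the submitters' statistics used the beads of each array. Whether a sample holds RNA of 1 or of several embryos is not given in the sources used here, nor are the Cre driver, the deleted exons and the genotype of the wild-type embryos in respect of Cre. All 6 arrays sat on 1 slide, so slide could not be tested as a batch, and scan day is not given in the sources used here.

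The deposited non-normalized table held, for each of 46632 probes and each array, a mean bead intensity, a bead number, a standard error of the bead intensities and a detection p-value, per the file headers. The submitters' processing notes name GenomeStudio, with no version. The deposited intensity was linear, had no background subtraction that the values show (none lay below 0), and had different medians on the 6 arrays. The deposited detection p-value moved in steps that correspond to 1603 negative control probes per array. The deposited bead number had a median of 35 or 36 per probe and array. A second deposited table, the series matrix, held processed intensity values on a linear scale, with values below 0. Each of its columns had a rank correlation of 1 with the non-normalized intensity of its own array, and the column medians were 18.53 (WT 1), 18.54 (WT 2), 18.54 (WT 3), 18.53 (KO 1), 18.51 (KO 2) and 18.54 (KO 3). The direction of the values was therefore that of the intensity. A rank correlation does not show the scale, which was read as linear from the range of values, with column minima between -26.88 and -24.4. The method of background subtraction and normalization is not given in the sources used here. Genome build and annotation are likewise not given in the sources used here.

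Intensities were background corrected by normexp with negative controls inferred from the detection p-values, given an offset of 16, quantile normalized and put on a log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value below 0.05 on at least 3 of the 6 arrays were tested, which left 20959 probes. On an array where a tested probe was not detected, its value near the floor entered the fit as it was. Gene names came from the platform's annotation table. Of all probes, 29976 carried 1 gene symbol, 10 carried several and 16646 were unnamed in that table. Entrez identifiers of 29921 probes were found in the current gene table, and 0 symbols needed an update. Of the tested probes, 15368 had 1 symbol, for 10099 genes, and 5591 were unnamed and entered the counts of probes only. A gene was represented by its tested probe with the highest mean over the 6 arrays. No coordinates were used.

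Each probe was fitted with lmFit and moderated with eBayes with a variance trend, as KO minus WT without covariates, and p-values were adjusted by Benjamini-Hochberg over the tested probes with a threshold of 0.05. Arrays, not beads, were the replicates. Adjusted p-values in the text are from this limma fit unless another test is named, intervals are 95% intervals of the fit, and all tests were two-sided. For a probe detected on no array of 1 group, a fold was given as a lower bound on the ratio of the observed means. This bound makes no allowance for the spread between arrays, which the interval of the fit gives. The bound set the brighter group's mean against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes.

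Before the data were examined, 23 gene lists were written down, covering BMP, other signalling pathways, lens regulators and other cell types that a dissected piece could hold. Each list was tested with camera with a preset inter-gene correlation of 0.01, on 1 probe per gene, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The rule for named genes was also set then. It took Acvr1 and Bmpr1a, then up to 12 genes with the largest rise and 12 with the largest fall past the threshold. As fewer than 20 genes passed, it took instead the 20 genes with the lowest p, as not passing, and left out predicted and clone names. It also took the 2 measured members of each list with the largest absolute log2 fold change. Other genes in the text were chosen outside the rule, Id1 to Id4, Smad7, Pax6 and Sox2 as well-known members of their lists, and the rest after their values were seen.

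The procedure was tested on 20 simulated data sets, in each of which 200 of 20959 probes were changed. They used the observed probe means and the moderated probe variances of the fit, equal in both genotypes, with noise independent between probes. The fit for KO minus WT recovered 14.5% of 2-fold, 58.7% of 4-fold and 93.9% of 8-fold changes, and 5.29% of its calls were false on average. A downward shift of all measured BMP target genes by 1.5-fold or by 2-fold was called in 20 of 20 simulations over 10099 genes, with noise independent between genes.

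Alternatives set before the data were examined covered the normalization, the background correction and its offset, the submitters' processed values (floored at 16 before log2), the detection filter, the variance model, array weights, the set test, the probe rule, the threshold, the replicate number as a block and the removal of each array in turn. Added after the data were examined were the removal of both WT 1 and WT 2, the Xist level and the pigment level (mean of Pmel and Dct) as covariates, and a minimum mean log2 value of 8. Lists of pigment-cell, epithelial and lens genes written for the closing tests are reported there. The number of arrays limits the precision of every value. The median SD of a probe was 0.44 among WT arrays and 0.30 among KO arrays on the log2 scale, and the median 95% interval of a log2 fold change was its value ± 0.86.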

Results

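Lens ectoderm was laser-dissected from mouse embryos at embryonic day 9.5, the stage at which the surface ectoderm over the optic vesicle thickens into the lens placode. Wild-type samples (WT 1 to WT 3) were set against samples in which type I BMP receptors had been deleted in the placode (KO 1 to KO 3), 3 arrays per genotype. The comparison asks which transcripts of the lens ectoderm depend on BMP receptor signalling at this stage. The arrays detected between 39.6% (WT 2) and 45.7% (KO 1) of the 46632 probes, and median raw intensities lay between 74.5 (WT 2) and 90.7 (WT 1). The labels number the samples of each genotype 1 to 3, and because the series text speaks of pooled RNA, p-values measure the spread between these samples, which may be partly technical.

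The deleted receptors were examined first. Acvr1 (chromosome 2), which encodes the type I receptor ALK2, was followed by 3 probes, of which only ILMN_2660103 was detected on all 6 arrays. Its normalized log2 intensity was 7.65 ± 1.05 (SD, n = 3) in WT and 6.91 ± 0.53 (SD, n = 3) in KO, a log2 fold change of -0.74 with a 95% interval from -2.12 to 0.64 (limma adjusted p = 0.989). The WT arrays ranged from 6.63 to 8.73 and the KO arrays from 6.49 to 7.51, so the genotypes overlapped. The log2 fold change was -1.24 without WT 1 and -0.20 without WT 2. Bmpr1a (chromosome 14), which encodes ALK3, was detected on every array by both of its probes. The brighter, ILMN_1251119, had 9.58 ± 0.36 in WT and 9.70 ± 0.11 in KO (SD, n = 3), a log2 fold change of 0.12 with an interval from -0.39 to 0.63 (limma adjusted p = 0.989). ILMN_2653312 had a log2 fold change of -0.09 with an interval from -0.62 to 0.45. Both intervals exclude a 2-fold loss of the Bmpr1a signal. Which exons were deleted and where these probes lie is not given in the sources used here, and a probe outside the deleted part checks nothing about the genotype labels. The Bmpr1a difference had the opposite sign without WT 1 (-0.08).

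BMP target genes, the transcripts that rise with BMP-SMAD signalling in many cell types, did not differ detectably between the genotypes as a group. Of 20 genes, 12 were measured, 8 with a higher and 4 with a lower mean in KO, and 0 passed over all probes or adjusted over the list alone. The mean log2 fold change was 0.08 and the median 0.20 (camera adjusted p = 0.899). Single arrays moved this mean, to 0.02 without WT 1, 0.19 without WT 2, 0.23 without KO 1 (adjusted p = 0.239, with the unadjusted camera p below 0.05), 0.04 without KO 2 and 0.04 without KO 3, and it was -0.015 with the pigment level as a covariate. Among the Id genes, which encode inhibitors of helix-loop-helix factors, log2 fold changes were 0.24 for Id1 (interval -1.06 to 1.53), 0.26 for Id2 (-0.64 to 1.17), 0.18 for Id3 (-0.58 to 0.93) and -0.35 for Id4 (-0.91 to 0.20). The second probes of Id1, Id2 and Id4 gave 0.64, -0.03 and 0.20, so the probes of Id2 and of Id4 differed in sign. Smad7, an inhibitory SMAD, had 0.07 (-0.48 to 0.61). The members with the largest differences were Gata2, at 0.52 (interval -0.82 to 1.86), and Sp5, at -0.51 (-2.11 to 1.09), and both changed sign without WT 2. Msx1, Msx2, Bambi and Gata3 were below the detection filter. The interval lay within a 2-fold change either way for 6 of the 12 members. For dim members this bounds the signal and not the transcript. Id4 was at 5.635 on KO 2 and 5.622 on KO 3, below the lowest detected values there (5.711 and 5.647).

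**Figure D1:**
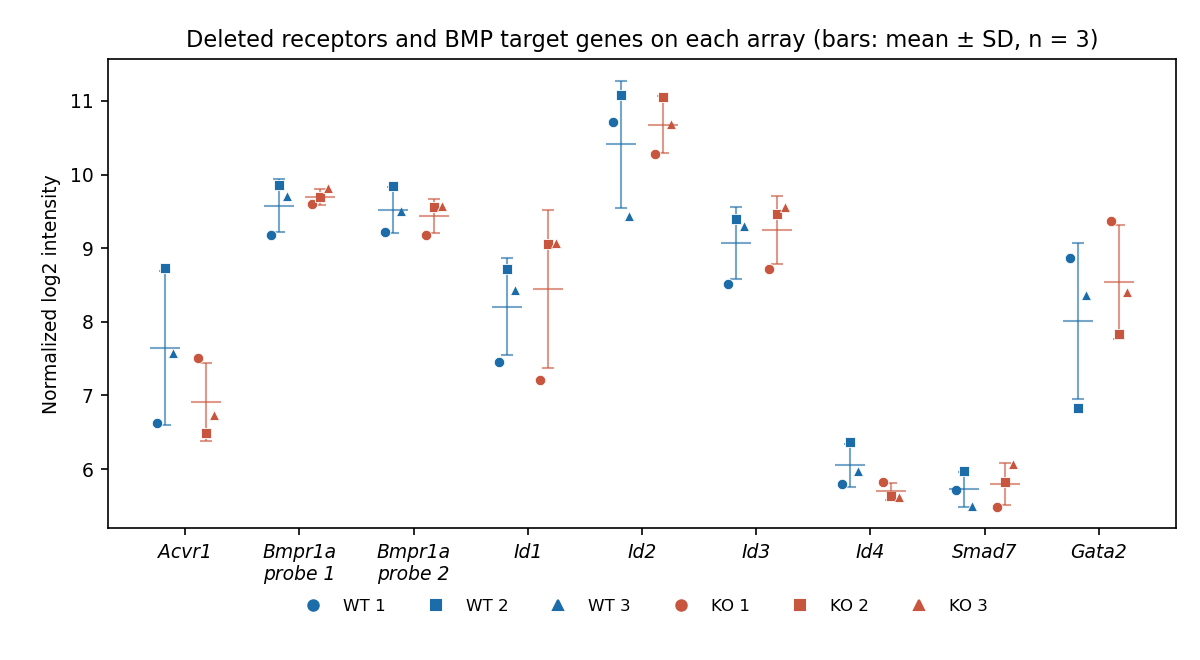
Normalized log2 intensity (vertical axis) of the Acvr1 probe and the Bmpr1a probes detected on all 6 arrays and of 6 BMP target genes, with 1 point per array, horizontal ticks for the mean and bars for the SD of 3 arrays. WT and KO arrays overlap for every probe shown, and Bmpr1a lies between 9.17 and 9.86 on every array.

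Other components of the pathway likewise gave values that did not pass. Of 12 measured BMP ligands and antagonists, 9 had a lower mean in KO, with a mean log2 fold change of -0.22 (camera adjusted p = 0.730). Gdf6, a BMP ligand needed for eye development, had -0.93 with an interval from -1.91 to 0.05, and its WT arrays all lay above its KO arrays. Grem1, a secreted BMP antagonist detected on 2 WT arrays and 1 KO array, had -0.75 (interval -2.19 to 0.69). The 15 measured receptors and SMADs of the BMP and TGF-beta families averaged 0.00 (camera adjusted p = 0.899), and Smad1, a BMP-regulated SMAD, had 0.53 (interval -0.06 to 1.12), while its 3 other probes gave -0.11 to -0.18.

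Across all 20959 tested probes, 0 passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.989. At an unadjusted p below 0.05 there were 941 probes, 606 with a higher and 335 with a lower mean in KO, where 1048 would be expected with no difference. The KO and WT arrays did not overlap for 2059 probes (9.82%), where chance gives 10%. For 8530 probes (40.7%) the 95% interval lay within a 2-fold change in either direction. A larger difference of the normalized signal is thus excluded for those probes one by one. For dim probes this does not exclude a larger change of the transcript, since values near the detection floor are compressed by the offset.

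The 20 named genes with the lowest p, none of which passed, split evenly into 10 with higher and 10 with lower values in KO, and their p ran from 1.83e-04 to 0.00365 (limma, unadjusted). Abcc10, which encodes an ABC transporter, had 7.75 ± 0.13 in WT and was detected on 0 of 3 KO arrays. Its observed mean was at least 4.26-fold lower in KO, with a log2 interval from -3.20 to -1.49 (limma adjusted p = 0.989). A second Abcc10 probe, detected on 2 arrays of each genotype, had a log2 fold change of -0.13. Pcdhb3, a clustered protocadherin, was likewise detected on no KO array. The observed Pcdhb3 mean was at least 2.00-fold lower in KO, with a log2 interval from -1.81 to -0.61. Among genes detected in both genotypes, lower KO values were found for Ten1, a telomere-capping subunit (log2 fold change -1.84, interval -2.79 to -0.89), the carbonic anhydrase gene Car13 (-1.82, -2.74 to -0.89), Fam104a (-1.32, -2.03 to -0.61, with -1.16 to -1.29 from its 3 other probes) and Gmnc, a geminin-family regulator of multiciliated cells (-1.27, -2.01 to -0.54). Smaller negative values belonged to Vkorc1, the vitamin K epoxide reductase (-1.06, and -1.13 from its second probe), Zkscan17 (-1.02), Iqgap1, a cytoskeletal scaffold (-0.99, with -0.06 and 0.14 from its other probes), and Csnk2a2, a catalytic subunit of casein kinase 2 (-0.86, and -0.42 from its second probe).

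Higher KO values were found for the zinc finger gene Zfp386 (2.20, interval 1.10 to 3.30), Tmem63a, an osmosensitive channel (2.04, 0.90 to 3.19), Slc22a5, the carnitine transporter (1.22, 0.59 to 1.85), and Tmem242 (1.08, 0.56 to 1.59). Inpp4b, a phosphoinositide phosphatase, Tedc1, Slc23a2, an ascorbate transporter, Ppdpf, Man2a1, a Golgi mannosidase, and Scaf1 were detected on all 3 KO arrays and on 0 WT arrays. For Inpp4b, Tedc1, Slc23a2, Ppdpf, Man2a1 and Scaf1 the observed means were at least 1.82-fold, 1.81-fold, 1.58-fold, 1.52-fold, 1.38-fold and 1.36-fold higher in KO, in that order. The lower ends of their log2 intervals were 0.64, 0.72, 0.50, 0.51, 0.46 and 0.41 in the same order. The Slc23a2 bound was that of 1 probe, since a second was detected on 2 arrays of each genotype and gave 0.06. Each of the 20 genes had an adjusted p of 0.989, so none of these differences exceeded what the spread between arrays gives over this many probes.

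The measured regulators of the lens placode gave no detectable group difference. Of 24 lens and preplacodal transcription factors, 16 were measured, 9 with a higher and 7 with a lower mean in KO, and 0 passed over all probes or adjusted over the list alone (camera adjusted p = 0.899). The mean log2 fold change was -0.08 and the median 0.08, so mean and median differed in sign, with a downward camera direction, and the mean was 0.13 without WT 2, 0.05 without KO 1 and -0.25 with the pigment level as a covariate. Pax6, required for lens and eye formation, had 10.92 ± 0.35 in WT and 10.98 ± 0.43 in KO (SD, n = 3), a log2 fold change of 0.05 with an interval from -0.51 to 0.62. Sox2, a partner of Pax6 in the placode, had 0.44 (interval -0.71 to 1.59). The largest differences were those of Bcl11a, a zinc finger regulator (-1.49, interval -3.62 to 0.63; -0.04 from its second probe, and -2.64 without KO 1 to -0.86 without KO 3), and Mab21l2, an eye morphogenesis gene (-1.01, -1.98 to -0.03, adjusted p = 0.989). The brighter Bcl11a probe was detected on 3 WT arrays but on only 1 KO array. Foxe3 and Pitx3 were below the detection filter. Of 24 crystallins and lens differentiation genes, 10 were measured and averaged 0.21 (camera adjusted p = 0.899). Cryge had 1.07 (interval -1.75 to 3.89, and -0.081 with the pigment level as a covariate) and Crygb 0.89 (-0.99 to 2.77). Without WT 2 the crystallin list passed camera with a preset correlation (mean 0.83, adjusted p = 0.00794), and the adjusted p with an estimated correlation was 0.942.

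Markers of neighbouring tissues were present on the arrays and varied within a genotype. The mean level of the measured optic vesicle markers had an SD of 0.86 among the WT arrays and 0.41 among the KO arrays, and that of the periocular mesenchyme markers 0.75 and 0.49. Of 20 optic vesicle and retina markers, 15 were measured, 11 with a lower mean in KO, with a mean log2 fold change of -0.28 (camera adjusted p = 0.808). Pmel, a melanosome protein, had -1.36 (interval -4.09 to 1.37), and Tbx5, a dorsal retina factor, had -1.08 (-2.89 to 0.72, and -0.33 from its second probe). The mean of this list was -0.72 without WT 2, where camera with a preset correlation passed (adjusted p = 0.0433) and camera with an estimated correlation did not (adjusted p = 0.942), and it was 0.13 without WT 3, -0.56 with array weights and -0.004 with the pigment level as a covariate. The last value is partly fixed in advance, since the pigment level is the mean of Pmel and Dct, which belong to this list. Periocular mesenchyme and neural crest markers averaged -0.36 over 10 measured genes (camera adjusted p = 0.730), with Col3a1, a fibrillar collagen, at -1.09 (-3.05 to 0.87) and Alx1, a frontonasal homeobox gene, at -0.86 (-2.46 to 0.75). Without WT 2 that list averaged -0.79 (adjusted p = 0.0195 with the preset and 0.942 with an estimated correlation).

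Blood markers averaged -0.39 over 9 measured genes and had the lowest unadjusted p of all lists (camera adjusted p = 0.730). Tal1, a haematopoietic regulator, had -1.15 (interval -2.79 to 0.50). Klf1, an erythroid factor, was detected on all 3 WT and on 0 KO arrays. Its observed mean was at least 1.91-fold lower in KO, with a log2 interval from -2.04 to -0.12 (limma adjusted p = 0.989). The blood list averaged -0.65 without WT 3 (camera adjusted p = 0.0183) and -0.72 without KO 1 (0.0491), and the adjusted p with an estimated correlation was 0.958 and 0.796 in these. Endothelial markers averaged -0.07 with a median of 0.03 over 8 genes, with Emcn at -0.84 (-2.59 to 0.90, and -0.22 from its second probe) and Flt1 at 0.37 (-0.48 to 1.21). Neuronal markers averaged -0.04 with a median of 0.08 over 6 genes, with Elavl4 at -0.41 (-1.29 to 0.46) and Map2 at -0.24 (-1.67 to 1.20), which turned to 0.39 without WT 1 and 0.079 without KO 2 and was 0.22 and 0.27 on its other probes. Camera gave a downward direction and an adjusted p of 0.899 for both, against the sign of their medians.

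Other signalling lists also stayed short of the threshold. Of 16 measured WNT targets and modulators, 11 had a lower mean in KO, with a mean of -0.17 (camera adjusted p = 0.808). The largest differences were those of Rnf43, a WNT receptor ubiquitin ligase (-1.01, interval -2.22 to 0.21), and Sfrp5, a secreted WNT antagonist (-0.98, -2.03 to 0.07). Sfrp5 was detected on 2 WT arrays and 1 KO array. FGF-ERK response genes averaged 0.11 over 13 genes, with Egr1, an immediate early factor, at 0.82 (-0.12 to 1.75) and Spry4, a feedback inhibitor of ERK signalling, detected on 3 KO arrays and 0 WT arrays. The bound on the observed Spry4 means was only 1.115-fold higher in KO, with a log2 interval from 0.09 to 1.02. The NOTCH pathway averaged 0.00 over 10 genes, with Notch1 at -0.59 (-1.90 to 0.72) and Hey1 at 0.44 (-0.51 to 1.40). Retinoic acid genes averaged 0.06 over 9 genes, with Rdh10, a retinol dehydrogenase, at 0.53 (-1.41 to 2.46) and Stra6, a retinol transporter, at -0.44 (-1.52 to 0.64, and -0.57 from its second probe). Rdh10 turned to -0.54 without WT 2, -0.13 with array weights and -0.032 with the Xist level as a covariate. The camera adjusted p was 0.899 for the last 3 lists.

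Lists on cell state and tissue structure did not pass either. Cell cycle genes averaged 0.02 over 20 measured genes, of which 14 had an interval within a 2-fold change, with Cdk1 at 0.76 (interval -0.29 to 1.80) and Birc5 at 0.65 (-0.13 to 1.42, with 0.10 and 0.15 from its other probes). For p53 targets and apoptosis genes the mean was 0.02, the median -0.06 and the camera direction downward over 14 genes, with the anti-apoptotic gene Bcl2l1 at 0.93 (-0.41 to 2.26, with -0.72 and 1.23 from its other probes) and Zmat3 at -0.85 (-1.98 to 0.27). Stress and immediate early genes had a mean of -0.02, a median of 0.03 and an upward camera direction over 11 genes, with the small heat shock gene Hspb1 at -0.93 (-3.15 to 1.29). Hypoxia and glycolysis genes averaged 0.04 over 15 genes, with Pgk1 at 0.22 (-0.09 without WT 1, -0.036 without KO 3) and Ankrd37 at 0.22 (-0.013 without KO 3). Extracellular matrix genes averaged -0.06 over 18 genes, with Tnc at 1.01 (-2.18 to 4.19, -0.32 with the pigment level as a covariate, and -0.49 and 0.38 from its other probes) and Col18a1, a basement membrane collagen, at -0.83 (-1.78 to 0.12). Epithelial adhesion genes averaged 0.03 over 16 genes, with Pard3, a polarity gene, at 0.69 (-0.27 to 1.65, and -0.40 from its second probe) and the claudin gene Cldn3 at -0.53 (-2.36 to 1.31), which turned to 0.15 without WT 1. Surface ectoderm and keratinocyte markers averaged 0.04 over 16 genes, with Krt5 at 0.75 (-0.16 to 1.66) and Ovol1 at 0.54 (-0.48 to 1.55). Regulators of other placodes averaged -0.41 over 7 genes, with Irx3 at -1.98 (-3.66 to -0.30, adjusted p = 0.989) and Ebf1 at -0.48 (-1.49 to 0.53, and -0.19 from its second probe). Irx3 was detected on 3 WT arrays but on only 1 KO array. The camera adjusted p of these 8 lists lay between 0.779 and 0.902, and 0 of all 23 lists had an unadjusted camera p below 0.05 or passed with the preset correlation, with an estimated correlation (lowest adjusted p = 0.930) or with fry (lowest adjusted p = 0.921).

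**Figure D2:**
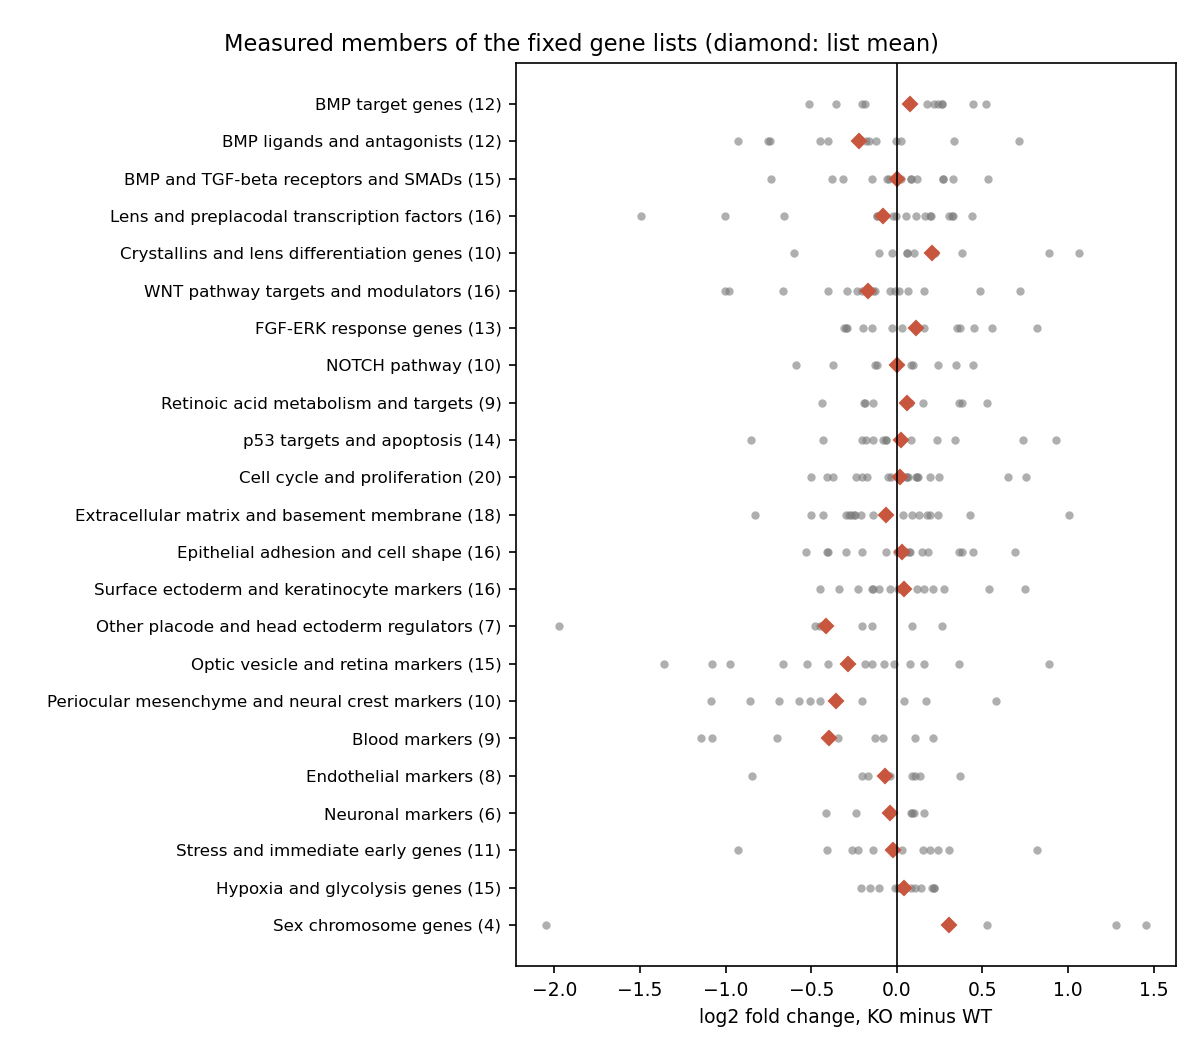
Log2 fold change, KO minus WT (horizontal axis), of every measured member of the 23 gene lists, with 1 grey point per gene, a diamond at the list mean and the number of measured genes in parentheses. No list passed camera with all 6 arrays, and list means lie between -0.41 (other placode regulators) and 0.30 (sex chromosome genes).

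Differences between arrays of one genotype were large for some lens, pigment and sex-chromosome genes. Maf, a regulator of lens fibre genes, was at 7.90, 11.65 and 9.06 on WT 1 to WT 3 and at 7.82, 10.99 and 10.79 on KO 1 to KO 3. Prox1, another lens regulator, was at 8.85, 11.18 and 8.82 in WT and at 8.67, 10.63 and 10.13 in KO. Pmel was at 9.85, 6.16 and 9.31 in WT and at 9.51, 5.97 and 5.75 in KO, and Dct, a melanin synthesis enzyme, was at 9.85, 5.34 and 9.80 in WT and at 9.21, 5.71 and 7.13 in KO. High Maf and Prox1 values and low Pmel and Dct values thus came together on WT 2, KO 2 and KO 3. Xist, transcribed from the inactive X chromosome, lay above 10 on WT 1, WT 2 and KO 3, and the Y-linked genes Eif2s3y, Uty and Kdm5d lay above 7 on WT 3, KO 1 and KO 2. Xist had a log2 fold change of -2.05 (interval -5.76 to 1.66; -1.05 on its second probe), and Uty had 1.46 (-1.26 to 4.16). For the sex chromosome list the mean was 0.30 over 4 measured genes (camera adjusted p = 0.899). Pairs of arrays correlated at a mean r of 0.855 within WT, 0.925 within KO and 0.893 between genotypes, across 20959 probes that are not independent replicates. WT 2 had the lowest mean correlation with the other arrays (0.859), followed by WT 1 (0.874). With both left out, 0 probes passed in limma (lowest adjusted p = 0.0963, 1194 at an unadjusted p below 0.05), in a fit that assumes the remaining WT array to vary like the KO arrays.

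**Figure D3:**
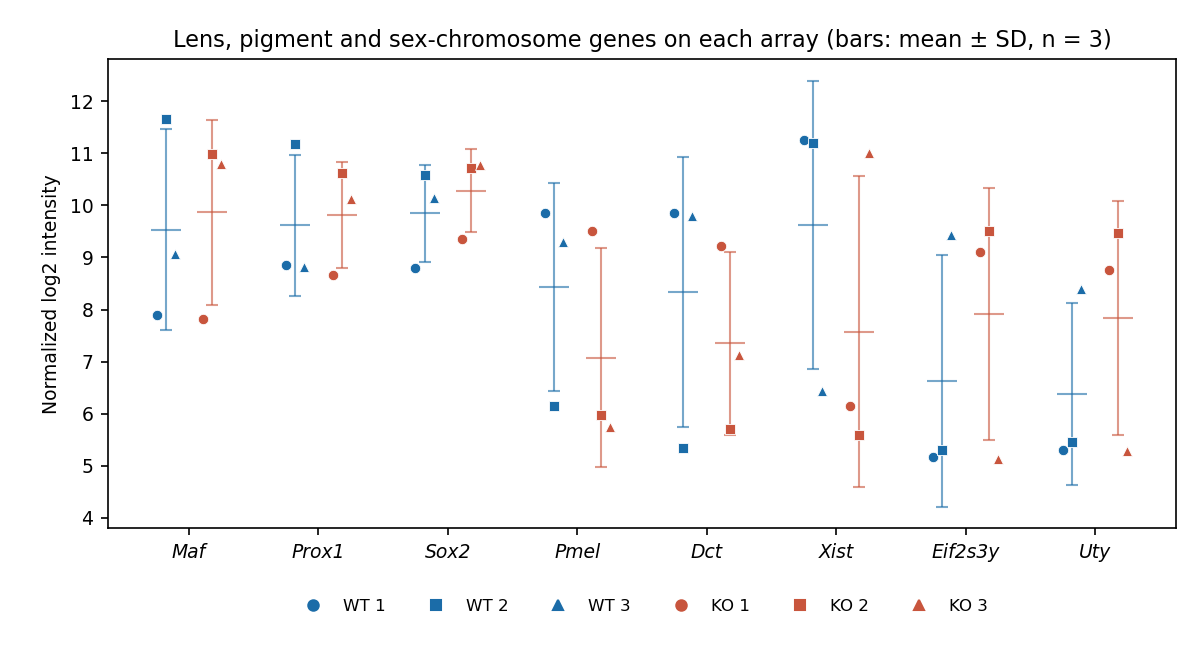
Normalized log2 intensity (vertical axis) of 3 lens regulators, 2 pigment genes and 3 sex-chromosome genes, with 1 point per array, horizontal ticks for the mean and bars for the SD of 3 arrays. Arrays of one genotype lie far apart, as for Pmel, between 6.16 and 9.85 in WT and between 5.75 and 9.51 in KO.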

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

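The tests chosen after the data were examined were those without both WT 1 and WT 2, with the Xist or the pigment level as a covariate, and with a mean log2 value of 8 or more. In all 25 alternatives limma called 0 probes (lowest adjusted p between 0.0963 and 1), and probes at an unadjusted p below 0.05 ran from 294 (mean log2 of 8 or more) to 1961 (no detection filter), with 1485 without WT 3, 579 without KO 3, 540 with the Xist and 1492 with the pigment covariate, 617 with detection on all 6 arrays and 521 at a detection p below 0.01. The replicate numbers did not meet the rule for pairing, a correlation above 0.1 for every number: deviations of same-numbered arrays correlated at 0.11, 0.14 and -0.01 (numbers 1, 2 and 3), WT 3 did not correlate best with KO 3 among the KO arrays, and with the number as a replicate block 0 probes and 0 lists were called (986 probes unadjusted, lowest list adjusted p 0.409). Leaving out 1 array at a time gave -1.24 (WT 1) to -0.20 (WT 2) for Acvr1, -0.081 (WT 1) to 0.26 (WT 2) for Bmpr1a, 0.02 (WT 1) to 0.23 (KO 1) for the BMP targets, -0.24 (WT 1) to 0.13 (WT 2) for the lens transcription factors, which were also at 0.05 without KO 1, -0.72 (WT 2) to 0.13 (WT 3) for the optic vesicle list, and 0 to 3 for the number of lists called. The 3 were crystallins, optic vesicle and periocular mesenchyme markers without WT 2, and 1 list, blood markers, was called without WT 3 and without KO 1; none was called with an estimated correlation (adjusted p 0.796 to 0.958). Ranges that crossed 0 were -0.074 to 0.94 for Gata2, -1.20 to 0.12 for Sp5 (0.12 without WT 2), -0.54 to 1.07 for Rdh10, -1.27 to 0.15 for Cldn3, -0.69 to 0.39 for Map2 (0.08 without KO 2), -0.09 to 0.43 for Pgk1 (-0.04 without KO 3) and -0.013 to 0.35 for Ankrd37. Without WT 1 and WT 2, 2 lists were called, crystallins (0.84, adjusted p 0.012) and optic vesicle markers (-1.11, adjusted p 3.26e-04), neither with an estimated correlation (0.894), and values were -0.004 for Bmpr1a, 0.019 for the lens transcription factors, -0.54 for Rdh10, 0.68 for Map2, 1.15 for Xist and -0.56 for Uty. The pigment covariate gave -0.015 for the BMP targets, -0.25 for the lens transcription factors (camera adjusted p 0.159), -0.004 for the optic vesicle list, -0.081 for Cryge, -0.32 for Tnc, 0.12 for Cldn3 and 0.075 for Map2. The optic vesicle list holds Pmel and Dct, from which this covariate was made, so its value is partly fixed in advance. The Xist covariate gave -0.032 for Rdh10. Array weights gave 0.008 for the lens transcription factors, -0.56 for the optic vesicle list (adjusted p 0.127) and -0.13 for Rdh10, and the mean of a gene's probes gave 0.042 for the lens transcription factors. With a mean log2 of 8 or more these were at 0.13, the BMP targets at 0.24 and the optic vesicle list at 0.17. Apart from the removal of arrays, which leaves fewer samples, the cause of these shifts was not tested. Of 1314 combinations of 64 named genes with an alternative, 1295 kept their direction and 0 were called. The 1295 is no measure of stability. The detection filters, the variance models and the replicate block cannot change the fold change of a probe. List means changed sign in 94 of 573 combinations. A list with no measured gene under a filter gave no value. Probes of the same gene agreed weakly, for a cause that was not tested: 2 bright probes of a gene (mean log2 of 9 or more) correlated in log2 fold change at r = 0.263 over 362 genes, and 2 probes of any brightness at 0.0867 over 2385 genes. Of the 66 genes followed through the alternatives, 19 had several tested probes, of opposite sign in 7, and 41 moved more than 1.5 times or reversed without 1 array.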

Other observations

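The tests chosen only after the result was seen were the counts of splits for probes past an adjusted p of 0.05 and at an unadjusted p below 0.05, the tests of pigment genes, epithelial genes and probe pairs, and the test of pooled sexes. The Xist and pigment covariates were also added after the data were examined, though the bounds for their residual SD were set before it was computed.

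Beyond the lens and pigment genes, lists of other tissues differed between arrays of one genotype. Endothelial markers lay, relative to each gene's mean over the 6 arrays, at 0.79 (log2) on WT 1 and 1.11 on KO 1, against -1.15 on WT 2, -0.82 on KO 2, -0.43 on KO 3 and 0.18 on WT 3. Surface ectoderm and keratinocyte markers were at 0.37 on WT 1 and 0.35 on KO 1 and between -0.30 and -0.09 on the other arrays. Periocular mesenchyme markers were at 0.81 on WT 1, 0.75 on WT 3 and 0.28 on KO 1, and at -0.78, -0.28 and -0.65 on WT 2, KO 2 and KO 3. Crystallins and lens differentiation genes were at 1.30 on WT 2, 0.12 on KO 2 and 0.27 on KO 3, and at -0.89, -0.83 and -0.40 on WT 1, WT 3 and KO 1. Optic vesicle and retina markers, which include Pmel and Dct, did not divide the arrays as these pigment genes did: they were at 1.12 on WT 3 and 0.37 on KO 3, -0.08 on WT 1 and -0.09 on KO 1, and -0.88 on WT 2 and -0.61 on KO 2. The retinal regulator Rax was at 7.72 on WT 3, 7.29 on KO 3, 6.87 on KO 1, 6.18 on WT 1, 5.79 on WT 2 and 5.77 on KO 2, and Nr2e1 was at 7.95 on WT 3 and 7.44 on KO 3 and between 5.37 and 5.75 on the other arrays.

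Probes of one gene did not always give the same difference. Tfap2a, a surface ectoderm regulator in the lens list, had a log2 fold change of 0.17 on its brightest probe, while on another the KO arrays lay at 8.90 or higher and the WT arrays at 7.87 or lower (limma unadjusted p = 0.00178, adjusted p = 0.989). Ezr, a cortical linker of epithelial cells, had 0.36 on its brightest probe and 1.93 on another (adjusted p = 0.989), and Cdh1, the epithelial cadherin, had 0.18 and 1.58. These probes were chosen after their values were seen.

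No probe passed an adjusted p of 0.05, and this was set against the spread of the replicates, pigment tissue and sex. Simulations at the moderated variances of the fit, with many probes changed at once, recovered 14.5% of 2-fold changes and 93.9% of 8-fold changes. A genotype effect of about 2-fold may thus have been missed. Most 8-fold changes would have been called at such variances if as many probes had changed. These rates need not hold for fewer changed probes, for variances that were not moderated or for noise shared between probes. They need not hold for falls of dim probes either. Pcdhb3, at a mean of 6.7 in WT and detected on no KO array, gave only a lower bound of 2.0-fold on its observed means. The median residual SD was 0.998 of its value with the Xist level as a covariate, which argues against sex as what hid a genotype effect across most probes. A median over all probes cannot tell whether sex hid an effect on a small share of them. With the pigment level the ratio was 0.888, which leaves pigment tissue open because it lies between the bounds of 0.7 and 0.9 set in advance. The 10 splits of the 6 arrays are too few for a share under 0.05: the count past an adjusted p decides nothing, since the real split gave 0 and all 10 of 10 gave at least that (highest other 50), 4 of 10 gave at least its 941 unadjusted probes (highest other 1890), and 5 of 10 at least the 14861 probes called from bead standard errors alone (highest other 15186). The split of WT 1, WT 3 and KO 1 against WT 2, KO 2 and KO 3 gave the 50 probes, and 9 of the 23 lists passed camera with the preset correlation but 0 with an estimated one (lowest adjusted p = 0.174). Most of the other splits that do not follow the genotype also gave 1 to 3 lists with the preset correlation. The genotype split gave 0, and no split gave a list with an estimated correlation. A list called with the preset correlation alone therefore need not reflect the genotype. Only the probes thus point to a structure of the samples besides the genotype, in a split picked as the highest of the 10. Bead errors called 60.4% to 78.0% of probes different between 2 arrays of one genotype and 62% to 73.6% between arrays of different genotype.

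Maf, Prox1, Sox2 and Cryab, lens genes named for the closing tests, and the pigment genes Pmel and Dct went opposite ways. The mean deviation of these lens genes, the lens level, was 1.27 on WT 2, 0.74 on KO 2 and 0.62 on KO 3. It was -1.27, -0.32 and -1.04 on WT 1, WT 3 and KO 1. In the same order, the mean of Pmel and Dct was 5.75, 5.84 and 6.44 against 9.85, 9.55 and 9.36. The list of lens transcription factors set in advance moved less, at 0.347, 0.172 and 0.145 against -0.411, 0.017 and -0.242. The crystallin list divided the arrays as the lens level did. Noise of single probes is argued against, since 2 bright probes of a gene followed the lens level alike (r = 0.529 across 362 genes, interval 0.450 to 0.599). Dilution by tissue without epithelial genes is argued against too, since it needs a slope of about 1 on the lens level. The 12 epithelial genes had slopes from -1.1 (Cldn3) to 0.442 (Epcam), with a median of -0.117 (interval -0.214 to -0.0336). Both intervals treat genes as units on the same 6 arrays and do not measure the spread between samples. Pigment-fated optic cup cells in some dissected pieces stay open as a source: 8 measured genes of an 18-gene pigment list had a median correlation with Pmel and Dct above that of 99.9% of random sets, led by Trpm1 (8.23, 7.94 and 7.43 on WT 1, WT 3 and KO 1, 5.37 to 5.54 elsewhere; 2 of its 4 probes followed), Mitf followed on 1 probe (r = 0.867) and less on its others (0.0451 on the brightest and 0.619), Slc16a1 followed weakly (0.307), but Slc24a5 ran opposite (9.20 to 9.34 against 9.63 to 9.89), and Mitf and Otx2 also belong to the optic vesicle list. Non-lens surface ectoderm in the piece and embryos of slightly different stage stay open as well, the latter a biological explanation that was not tested because the labels give every embryo the same day. Genotype alone does not account for this difference, since each side holds arrays of both genotypes. The sides are unevenly spread over the genotypes, however, with WT 2, KO 2 and KO 3 against WT 1, WT 3 and KO 1. With so few arrays a contribution of the genotype cannot be excluded.

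Xist was at 11.3, 11.2 and 11.0 on WT 1, WT 2 and KO 3 and at 6.43, 6.15 and 5.59 on WT 3, KO 1 and KO 2, with Y-linked genes the other way round. A pool of embryos of both sexes would show both, but the lower of the Xist and the Y-linked signal, each as a share of its highest array, was at most 6.08% on any array. This argues against samples of mixed sex and is consistent with each array holding RNA of 1 embryo, or of several of the same sex, which the arrays cannot separate. The sexes are unevenly spread over the genotypes, with high Xist on WT 1 and WT 2 and on KO 3 alone, and with the Xist level as a covariate 0 probes were called (540 at an unadjusted p below 0.05).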
